A study of Mus musculus with 6 samples.

How the data were processed

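Expression was measured in GFP-sorted calvarial osteoblasts of 1-week-old mice, 3 samples with the Rs1 receptor and 3 controls without it, with 1 array each. Per the labels' protocols, calvariae were pooled by genotype, the sutures were removed, cells were released by sequential collagenase and trypsin digestion, and the later fractions were sorted on GFP with a gate set on cells of mice without the reporter. Per the labels' protocols, total RNA was extracted with a PicoPure kit and amplified and biotin-labelled with NuGEN whole-transcript reagents. The platform, per the probe table's header, is an Affymetrix Mouse Gene 1.0 ST array. The values deposited by the authors are 1 signal per probe set and array on a log2 scale. The log base is read from the values, which run from 2.01 to 14.3 as log2 of a scanner signal does. They were already normalized when deposited, since quartiles and medians of the 6 arrays were nearly equal. The scanner, software, background correction, summarization and normalization method are not given in the sources used here, so their effect on the differences was not tested beyond renormalizing the deposited values.

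The table held 35518 probe sets and no missing value. The probe table listed 23385 of them, 21780 with 1 gene symbol and 1605 with several, and 12133 were unnamed here. Of the probe sets with 1 symbol, 21689 matched the reference gene table of mouse assembly GRCm38.p6 by gene identifier, and 0 symbols had to be updated. Only probe sets with 1 symbol were used for genes. For the 998 genes with several, the probe set with the highest mean over the 6 arrays stood for the gene, which left 19935 genes. List genes without a probe set of 1 symbol in the probe table, among them Bglap, Spp1, Runx2 and Gnas, were not analysed here. No filter on dim signal was applied in the main comparison, and no coordinates are given because the sources name no genome build.

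Rs1 was compared with control in limma 3.58.1 (R 4.3.3) with lmFit and eBayes on the log2 values, with no covariate, as a two-sided moderated test with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Differences are Rs1 minus control on the log2 scale with limma's SE, and group values are means ± SD over 3 arrays. The 33 gene lists covered osteoblast biology, signalling downstream of Gs, the cell cycle, metabolism, stress, and markers of other cell types that the sort could hold. They were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, beside camera with an estimated correlation and fry. A list score is the mean over members of the deviation of an array from the gene's mean over the 6 arrays. Scores of the 2 groups were compared with two-sided exact permutation tests, which cannot give a p under 0.1 with 3 against 3 arrays.

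Genes were named by a rule written before the data were examined. It took up to 12 genes in each direction past the threshold with groups that do not overlap and mean signal above the median, leaving out predicted genes, clone names, olfactory and vomeronasal receptors and antigen receptor segments. As none passed, it took the 6 with the smallest p in each direction that met the other conditions. It also took the 2 members of each list with the smallest p, and Htr4, Sost, Dkk1, Col1a1, Tnfsf11 and Bglap (no usable probe set) whatever they showed. Lists, named genes and most alternatives were fixed before the data were examined. The alternatives were quantile normalization, a common median, a filter on dim genes, the mean of all probe sets of a gene, an offset of 32 on the linear scale, a variance trend with robust estimation, the replicate number as a block, each array left out in turn, all probe sets, other thresholds, and other set tests. Leaving out controls 1 and 2 together and the macrophage or Y-linked score of each array as a covariate were added after the data were seen, as was the split of the cAMP and CREB list by its overlap with the stress list. Where a group was left with 1 array, its spread was taken from the other group.

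The procedure was tested on simulated data with the spread of these arrays. With 200 of 19935 genes changed, limma recovered 2.99% of genes changed by 0.5 log2 units, 64.6% of those changed by 1 and 95.5% of those changed by 2 (20 simulations). Changes well under 2-fold in single genes were therefore mostly below detection with 3 arrays per group. In 200 simulated lists of 29 genes with no shift, camera with the preset correlation called 3% when members were independent and 31% when they were correlated at 0.2, and with an estimated correlation it called 0.5% and 2%. With a shift of 0.35 the estimated correlation called 97% of lists correlated at 0.2. A simulated list was called at an unadjusted p under 0.05, a looser threshold than the p adjusted over the lists that was used for the real ones. Power at the adjusted threshold was not simulated, so the 97% does not measure it.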

Results

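Gene expression was measured in osteoblasts, the bone-forming cells, taken straight from the skull bones (calvariae) of 1-week-old FVB/N mice without cell culture. The mice carried a histone-GFP reporter switched on in osteoblasts through a collagen I promoter, and cells were sorted by GFP. In 3 samples the same promoter also switched on Rs1, an engineered receptor that signals through the Gs protein without a ligand. The 3 control samples came from mice with the reporter and without Rs1, per the sorting protocol, although another label field calls the control cells wild type. Each sample was hybridised to 1 Affymetrix mouse gene array with 35518 probe sets in the deposited table. The labels name the samples biological replicates and do not say how many animals or separate pools stood behind each, so the p-values measure the spread between these samples. Median log2 signal per array lay between 6.79 and 6.86. Pearson's r over all probe sets was 0.964 to 0.970 within groups and 0.962 to 0.970 between groups, values set mostly by differences between probe sets, which leave little room for a difference between groups to show. Precision was limited by the number of arrays, 3 in each group.

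The study asked how Gs signalling through Rs1 alters the osteoblast transcriptome in mice with a large increase in bone formation. No single gene of the 19935 tested passed the threshold in limma (smallest adjusted p = 0.779). Among the genes nearest to it that met the naming rule, 6 had higher mean signal in Rs1 osteoblasts. Lipi, a membrane-bound lipase that acts on phosphatidic acid, measured 8.33 ± 0.12 (log2, SD, n = 3) in Rs1 and 6.12 ± 0.69 (n = 3) in control osteoblasts, a 4.63-fold difference. Lgals2, which encodes the carbohydrate-binding protein galectin-2, measured 9.01 ± 0.56 against 7.28 ± 0.09, a 3.31-fold difference. Fv1, which restricts infection by murine leukemia viruses, differed by 1.07 ± 0.15 (log2, Rs1 minus control ± SE). Dennd4a, which encodes an activator of Rab proteins, differed by 0.73 ± 0.12, although its 9 probe sets did not all have the same sign. Nkiras1, a Ras-like regulator of NF-kappaB inhibitors, differed by 0.73 ± 0.12. Pgd, an enzyme of the pentose phosphate pathway, differed by 0.56 ± 0.09.

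The 6 genes nearest the threshold that met the naming rule with lower mean signal in Rs1 osteoblasts differed by less than 1 log2 unit. Ddx1, an RNA helicase, measured 10.09 ± 0.02 in Rs1 and 10.89 ± 0.11 in control osteoblasts (log2, SD, n = 3 each). Thbd, which encodes the anticoagulant membrane protein thrombomodulin, differed by -0.81 ± 0.16, and Gstm1, a glutathione S-transferase, by -0.75 ± 0.11 (log2 ± SE). The values were -0.66 ± 0.11 for the growth factor gene Fgf9, -0.62 ± 0.12 for Asxl2, which encodes a Polycomb-associated protein, and -0.58 ± 0.10 for Cmklr1, a receptor for chemerin. In each of these 12 genes the 3 arrays of one group lay wholly above or below the 3 of the other. The naming rule required this separation, so it is no evidence of a difference. Their adjusted p in limma lay between 0.779 and 0.833. Groups did not overlap in 2189 genes, or 11.0% of those tested, where chance gives 10% for 3 against 3 arrays. At an unadjusted p under 0.05, limma counted 1149 genes, 655 higher and 494 lower in Rs1, where 997 would be expected by chance. Without control 3 limma called 1 gene, Gm6377, a predicted gene named here after its values were seen (log2 difference -2.28, adjusted p = 0.0161), and with all arrays its adjusted p was 0.837.

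**Figure D1:**
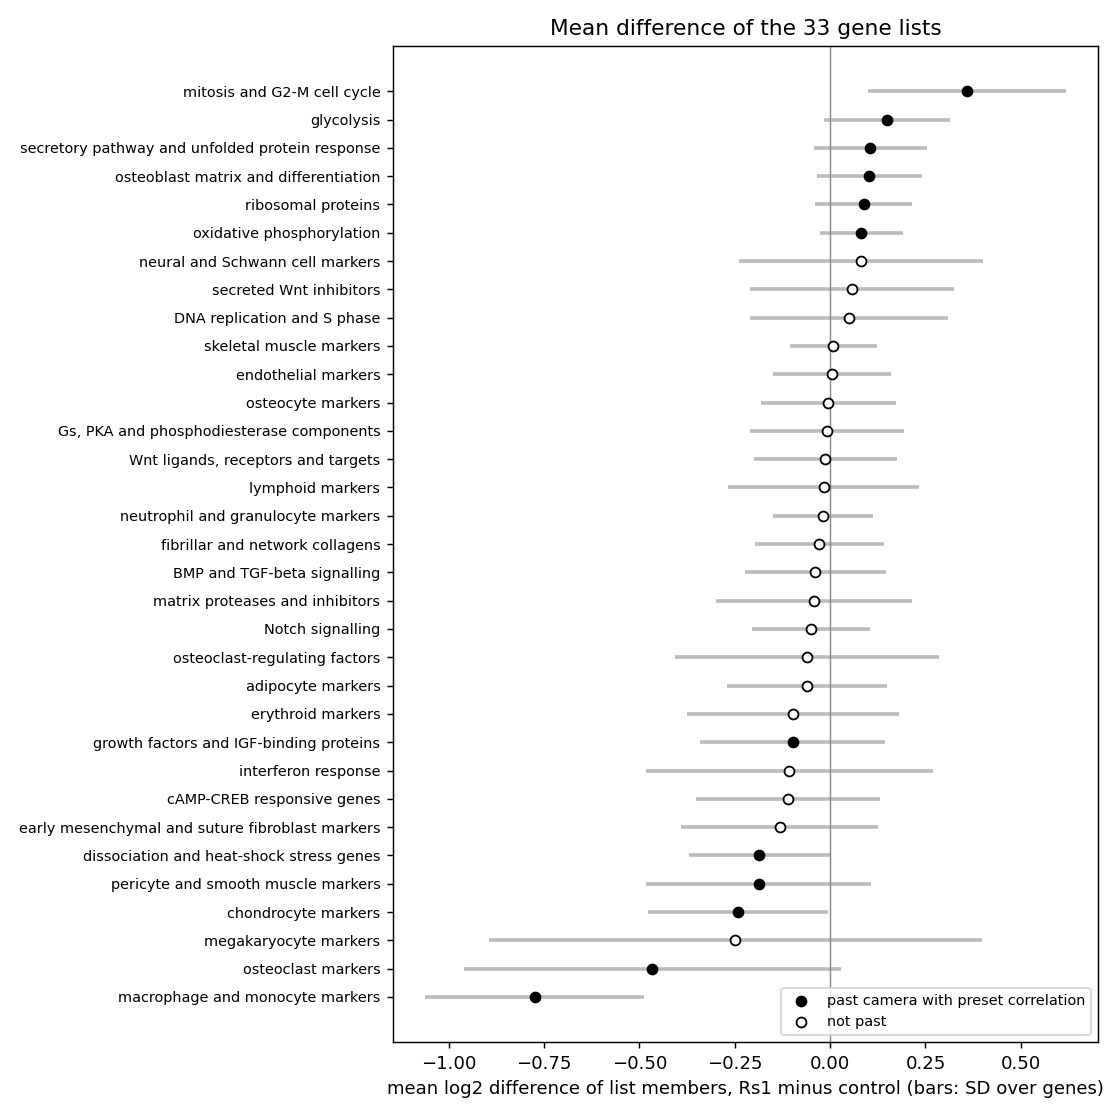
Mean log2 difference (Rs1 minus control, x axis) of the members of each of the 33 gene lists (y axis), with bars for the SD over genes; filled points passed camera with the preset correlation and open points did not. The mitosis list lay highest, at 0.36, and the macrophage list lowest, at -0.77.

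Gene lists fixed before the data were examined gave shifts of small size. Of 33 lists, 12 passed limma's camera test with its preset correlation between genes, 6 higher and 6 lower in Rs1. None passed with an estimated correlation (smallest adjusted p = 0.420) or in fry's directional test (smallest adjusted p = 0.183), and fry's test of change in either direction called 1 list, the growth factors (adjusted p = 0.00185). The array means of 7 lists did not overlap between the groups, and 6 of these were among the 12. For each list, an exact permutation test of 3 against 3 arrays cannot give a p under 0.1. No list member passed the threshold over all genes.

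Genes of mitosis and the G2-M phase of the cell cycle were higher in Rs1 osteoblasts. Of 29 measured members, 27 were higher and 2 lower, with a mean log2 difference of 0.36 (1.28-fold; camera adjusted p = 7.84e-10). With an estimated correlation the adjusted p was 0.420, from an unadjusted p of 0.0478. Prc1, which bundles the microtubules of the spindle midzone, differed by 0.64 ± 0.14 (log2 ± SE), and Knl1, a kinetochore scaffold, by 0.65 ± 0.16. Cdk1, the kinase that drives entry into mitosis, differed by 0.88 ± 0.23 and is named after its values were seen. The 3 Rs1 arrays lay above the 3 control arrays in 10 members and in the mean of the list. Adjusted over the list alone, 7 members passed. The genes of DNA replication and S phase did not pass, with 19 of 29 members higher, a mean of 0.05 (0.02 without control 1 and 0.10 without control 2) and an adjusted p of 0.344. In that list Ccne2, a cyclin of S phase entry, differed by 0.50 ± 0.15, and Fen1, a flap endonuclease of DNA replication, by -0.55 ± 0.24. The mitosis list exceeded the S phase list by 0.31 (log2, Rs1 minus control; exact permutation p = 0.1, the smallest possible).

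**Figure D2:**
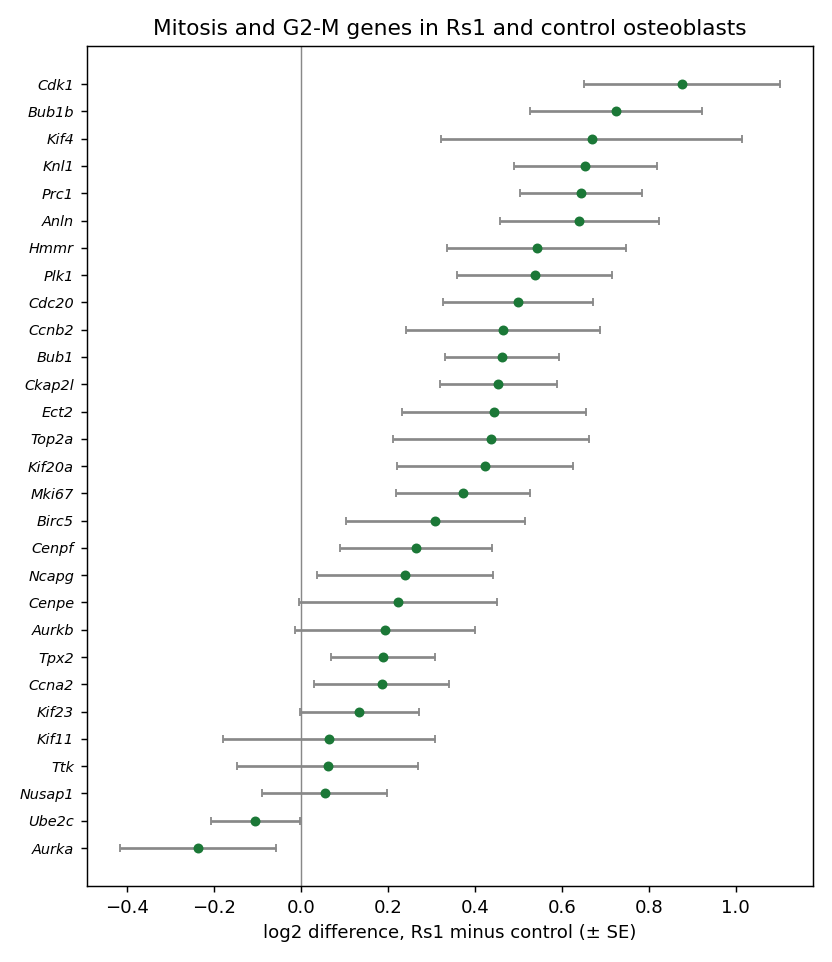
Log2 difference (Rs1 minus control, x axis) of the 29 measured mitosis and G2-M genes (y axis), points with bars of ± SE from limma. The differences ran from -0.24 for Aurka to 0.88 for Cdk1, and 27 of the 29 lay above 0.

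Of the lists of protein secretion, energy metabolism, ribosomal proteins and osteoblast differentiation, 5 passed the preset test with small positive means, and no call held with an estimated correlation. In the secretory pathway and unfolded protein response list 27 of 32 members were higher (mean log2 difference 0.11, adjusted p = 0.00729; adjusted p = 0.420 with an estimated correlation). P4ha2, a prolyl hydroxylase of collagen, differed by 0.54 ± 0.13 and Pdia6, a disulfide isomerase, by 0.33 ± 0.10. In glycolysis 12 of 14 members were higher (mean 0.15, adjusted p = 0.0251; adjusted p = 0.420 with an estimated correlation), with Pkm at 0.52 ± 0.17 and Pgk1 at 0.30 ± 0.13. In oxidative phosphorylation 23 of 29 were higher (mean 0.08, adjusted p = 0.0251; adjusted p = 0.420 with an estimated correlation), with Sdhc at 0.32 ± 0.13 and Ndufa5 at 0.19 ± 0.10. In the osteoblast matrix and differentiation list 16 of 19 were higher (mean 0.10, adjusted p = 0.0310; adjusted p = 0.633 with an estimated correlation), and 1 member, Phospho1, had an unadjusted limma p under 0.05. The abundant matrix genes Col1a1, Col1a2 and Sparc differed by 0.04, 0.04 and 0.0066, and Omd by -0.21. Phospho1 and Alpl, the phosphatases of matrix mineralisation, differed by 0.32 ± 0.12 and 0.27 ± 0.13. Of the ribosomal protein genes 19 of 21 were higher (mean 0.09, adjusted p = 0.0470; adjusted p = 0.420 with an estimated correlation), with Rpl12 at 0.60 ± 0.29 and Rps3 at 0.20 ± 0.11. All 5 calls ended after quantile normalization, at means of 0.07 (secretory), 0.13 (glycolysis), 0.06 (oxidative phosphorylation), 0.07 (osteoblast) and 0.06 (ribosomal). They also ended without control 1, at means of 0.07, 0.12, 0.08, 0.06 and 0.08 in the same order. With the macrophage score as a covariate all but the oxidative phosphorylation call ended, although the means stayed at 0.09 (secretory), 0.12 (glycolysis), 0.09 (osteoblast) and 0.09 (ribosomal). The same 4 calls ended without controls 1 and 2, at means of 0.08, 0.11, 0.05 and 0.08. Without Rs1 array 1 the osteoblast, oxidative phosphorylation and ribosomal calls ended (means 0.06, 0.07 and 0.08), and without Rs1 array 2 the glycolysis, oxidative phosphorylation and ribosomal calls (means 0.14, 0.08 and 0.08). The last 2 also ended without control 3 (means 0.07 and 0.09) and the ribosomal call without control 2 (mean 0.10), so that over 16 other settings the secretory call held in 12, oxidative phosphorylation in 10, glycolysis and osteoblast in 9 each and ribosomal proteins in 3.

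Transcripts of the main bone collagen and of the osteocyte markers showed no detectable difference. Col1a1, the chain that makes up most of bone collagen, measured 13.26 ± 0.12 in Rs1 and 13.22 ± 0.03 in control osteoblasts (log2, SD, n = 3 each), and its difference had a 95% interval of -0.20 to 0.29. In the list of fibrillar and network collagens 8 of 20 members were higher (mean -0.03, adjusted p = 0.828), with Col24a1 at 0.31 ± 0.10 and Col8a1 at -0.59 ± 0.31 (0.090 without controls 1 and 2, the arrays with the highest macrophage scores). In the osteocyte list 8 of 17 were higher (mean -0.004, adjusted p = 0.983), with Hyou1, also a chaperone of the secretory pathway, at 0.33 ± 0.11 and Kera at -0.23 ± 0.12. The signal of Kera (4.73 in Rs1, 4.96 in control) lay below the lower quartile of every array. Sost, which encodes the osteocyte Wnt antagonist sclerostin, differed by -0.01 ± 0.12 and the Wnt antagonist Dkk1 by 0.04 ± 0.21, both with either sign under other settings. In the matrix proteases and inhibitors 14 of 22 were higher (mean -0.04, median 0.03, adjusted p = 0.989). The mean ran from -0.07 without Rs1 array 2 to -0.02 without Rs1 array 3. Timp1, an inhibitor of metalloproteinases, differed by 0.32 ± 0.13 and the collagenase gene Mmp13 by 0.19 ± 0.10. Early mesenchymal and suture fibroblast markers did not pass, with 14 of 21 lower (mean -0.13, adjusted p = 0.0545), and among them Aspn differed by -0.40 ± 0.17 and Dpt by -0.83 ± 0.36. The mean of this list was -0.08 without Rs1 array 1, -0.05 without control 2 and 0.05 without controls 1 and 2. It was past the threshold at -0.22 without control 3 (adjusted p = 0.00708), and passed in 6 of 16 other settings in all (smallest adjusted p = 0.535 with an estimated correlation).

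Markers of macrophages and osteoclasts were lower in the Rs1 arrays as groups. Of 19 macrophage and monocyte markers, all 19 were lower (mean log2 difference -0.77, adjusted p = 1.14e-05; adjusted p = 0.633 with an estimated correlation). Cd68 measured 9.13 ± 0.61 in Rs1 and 10.25 ± 0.96 in control osteoblasts (log2, SD, n = 3 each), and the leukocyte gene Ptprc differed by -1.22 ± 0.48. The control arrays differed widely among themselves, with list scores of 1.51, 0.59 and -0.93 for controls 1, 2 and 3, against 0.23, -0.66 and -0.73 for the Rs1 arrays. Without control 1 the mean was -0.21 (adjusted p = 0.146), without control 3 it was -1.43, and without controls 1 and 2 it was 0.54. Of 14 osteoclast markers, 13 were lower (mean -0.47, adjusted p = 2.08e-06; adjusted p = 0.420 with an estimated correlation). Atp6v0d2, a proton pump subunit needed for osteoclast fusion, measured 7.75 ± 0.57 in Rs1 and 9.70 ± 1.11 in control osteoblasts, and Ostm1, a partner of the osteoclast chloride transporter, differed by -0.50 ± 0.17. Without controls 1 and 2, which had the highest macrophage scores, the osteoclast mean was -0.01 (adjusted p = 0.990), and with the macrophage score as a covariate it was -0.25.

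**Figure D3:**
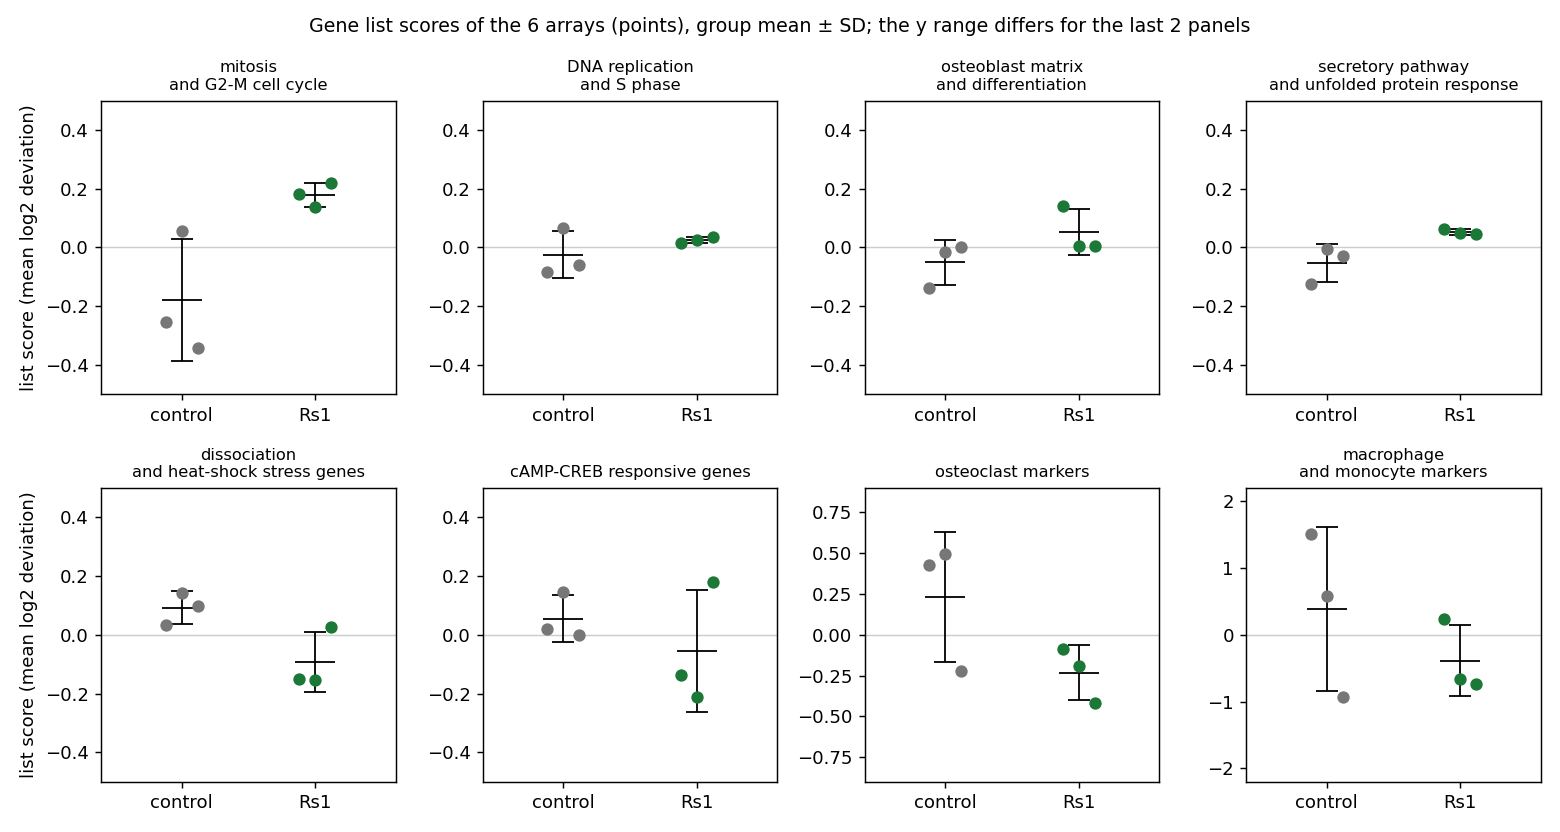
List score of each array (y axis, mean log2 deviation of the members from their means over the 6 arrays) for 8 gene lists, with control arrays in grey and Rs1 arrays in green, and lines for group mean ± SD (n = 3 each). In the mitosis panel the Rs1 scores of 0.14 to 0.22 lay above the control scores of -0.34 to 0.06, and in the macrophage panel the groups overlapped.

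Lists of stress genes, chondrocytes, mural cells and growth factors were also lower on average in Rs1. Array means of the chondrocyte, pericyte and growth factor lists overlapped between the groups (exact permutation p = 0.3, 0.2 and 0.3). Of the dissociation and heat-shock stress genes 19 of 25 were lower (mean -0.19, adjusted p = 2.12e-05; adjusted p = 0.420 with an estimated correlation), and no array of one group overlapped the other in the list mean. Ier3, an immediate early gene, differed by -0.41 ± 0.12 and the chaperone gene Hsph1 by -0.39 ± 0.12. Without the 6 members shared with the cAMP and CREB list the mean was -0.15 (19 genes, adjusted p = 6.41e-04; adjusted p = 0.420 with an estimated correlation). Of the chondrocyte markers 13 of 16 were lower (mean -0.24, adjusted p = 0.00148; adjusted p = 0.420 with an estimated correlation), with Comp at -0.54 ± 0.17 and Hapln1 at -0.60 ± 0.22. Of the pericyte and smooth muscle markers 10 of 13 were lower (mean -0.19, adjusted p = 0.0219; adjusted p = 0.420 with an estimated correlation), with Abcc9 at -0.57 ± 0.14 and Mylk at -0.43 ± 0.14. Of the growth factors and IGF-binding proteins 19 of 29 were lower (mean -0.10, adjusted p = 0.0310; adjusted p = 0.420 with an estimated correlation), with Fgf9 as above and Fgf2 at -0.50 ± 0.13, and Fgf9 alone passed when adjusted over the list alone. Without control 2 the chondrocyte, pericyte and growth factor calls ended (means -0.11, -0.13 and -0.04), and without control 1 the chondrocyte mean was -0.37. The pericyte call also ended without Rs1 array 2 or with the macrophage score as a covariate (mean -0.13 in each). The growth factor call ended without Rs1 array 1 (mean -0.07). Without controls 1 and 2 both calls ended, at means of -0.08 and -0.03 (adjusted p = 0.391 each).

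Genes tied to the Gs pathway itself did not pass as a group with all arrays. Of the genes responsive to cAMP and CREB, 9 of 24 were higher and 15 lower in Rs1 (mean -0.11, adjusted p = 0.0523), and the array means overlapped. The call rested on single arrays and settings. Without Rs1 array 3 the mean was -0.23 and past the threshold (adjusted p = 4.62e-04), without Rs1 arrays 1 or 2 it was -0.07 or -0.03, without control 2 it was -0.06, and the list passed in 8 of 16 other settings (smallest adjusted p = 0.452 with an estimated correlation). Of its members, 6 (Nr4a1, Fos, Fosb, Junb, Dusp1 and Atf3) were also on the dissociation and heat-shock stress list, and all 6 were lower (mean -0.31). The other 18 had a mean of -0.04, with 9 higher and 9 lower (adjusted p = 0.461). Dusp1, a phosphatase of MAP kinases, differed by -0.40 ± 0.17 and the clock gene Per1 by -0.34 ± 0.14. Of the Gs, PKA and phosphodiesterase components 13 of 31 were higher (mean -0.01, adjusted p = 0.881), with the adenylyl cyclase gene Adcy7 at -0.33 ± 0.12. Gnas, Prkaca and Rapgef4 of this list had no usable probe set and were not tested. Htr4, the mouse gene of the serotonin receptor from whose human counterpart Rs1 was engineered, measured 6.38 ± 0.32 in Rs1 and 5.96 ± 0.09 in control osteoblasts (log2, SD, n = 3 each). Its probe set is not a check of the transgene. Among secreted Wnt inhibitors 10 of 13 were higher (mean 0.06, adjusted p = 0.487), with Sfrp1 at 0.67 ± 0.26 and Sfrp5 at 0.18 ± 0.12. The mean of this list was 0.02 without Rs1 array 1, 0.03 without control 1 and -0.02 with dim genes removed. Among Wnt ligands, receptors and targets 11 of 29 were higher (mean -0.01, adjusted p = 0.698), with the cyclin gene Ccnd1 at 0.40 ± 0.11 and Nkd1 at 0.29 ± 0.11.

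Other signalling lists did not pass either with all arrays. In BMP and TGF-beta signalling 22 of 32 members were lower (mean -0.04, adjusted p = 0.176), with Id2, a target of BMP signals, at -0.49 ± 0.10 and the BMP antagonist Grem1 at 0.40 ± 0.09. Without Rs1 array 2 this list had a mean of -0.09 and passed (adjusted p = 0.0103; 0.731 with an estimated correlation). Its direction rested on single arrays, with a mean of 0.0068 without Rs1 array 3, -0.01 without control 3 and -0.08 without control 1. In Notch signalling 8 of 15 were lower (mean -0.05, adjusted p = 0.176), with Hes1 at -0.39 ± 0.16 and Lfng at -0.26 ± 0.12. Of the factors that regulate osteoclasts 9 of 16 were higher (mean -0.06, median 0.05, adjusted p = 0.989), and the mean ran from -0.15 without control 3 to -0.0025 without control 1 and was 0.13 without controls 1 and 2. Tnfsf11, which encodes the osteoclast-inducing cytokine RANKL, differed by 0.31 ± 0.14 and Wnt5a by -0.25 ± 0.11. In the interferon response 11 of 16 were lower (mean -0.11, adjusted p = 0.337). The mean was -0.03 without control 1, -0.05 without Rs1 array 3, -0.17 without Rs1 array 2, -0.20 without control 3 and 0.09 without controls 1 and 2, the arrays with the highest macrophage scores. The list held Cxcl10 at -1.33 ± 0.63 and Ifit1 at -0.19 ± 0.12, and both also turned without controls 1 and 2.

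None of the remaining cell type lists passed. Megakaryocyte markers had a mean of -0.25 (6 of 8 lower, adjusted p = 0.373), which was -0.16 without Rs1 array 2, -0.39 without control 3 and 0.04 without controls 1 and 2, with Pf4, also transcribed in macrophages, at -1.84 ± 0.70 and Gp5 at -0.13 ± 0.14 (0.082 without controls 1 and 2). Erythroid markers had a mean of -0.10 and a median of 0.02 (adjusted p = 0.530), with Car2, which osteoclasts also express, at -0.70 ± 0.26 and Tfrc at -0.50 ± 0.31. Only 10 of the 18 erythroid genes were measured, and none of the hemoglobin genes was among them. Neutrophil markers had a mean of -0.02 (adjusted p = 0.706), with Prtn3 at -0.27 ± 0.15 and Ctsg at 0.20 ± 0.14. Lymphoid markers had a mean of -0.02 (adjusted p = 1.00), with Cd79a at 0.35 ± 0.14 and Blnk at -0.79 ± 0.37. The signal of Cd79a (4.16 in Rs1, 3.81 in control) lay below the lower quartile of every array. Endothelial markers had a mean of 0.005 (adjusted p = 0.989), with Eng at 0.37 ± 0.17 and Plvap at 0.14 ± 0.11. Skeletal muscle markers had a mean of 0.009 (adjusted p = 0.989), with Tnnc2 at 0.24 ± 0.11 and Myl1 at -0.13 ± 0.10. Adipocyte markers had a mean of -0.06 (adjusted p = 0.854), with Lpl at -0.62 ± 0.34 (0.055 without controls 1 and 2) and Pparg at 0.16 ± 0.12. Neural and Schwann cell markers had a mean of 0.08 (adjusted p = 0.698), with Cdh19 at -0.19 ± 0.11 and the tubulin gene Tubb3 at 0.95 ± 0.19, and Tubb3 passed when adjusted over the list alone. Cdh19 (3.55 in Rs1, 3.74 in control) also lay below the lower quartile of every array. With 1 array left out in turn, 10 of the 21 lists that did not pass had means of either sign: osteocyte, Gs and PKA, Wnt ligands, BMP and TGF-beta, collagens, neutrophil, lymphoid, endothelial, skeletal muscle and adipocyte. In 6 of the lists that did not pass (erythroid, skeletal muscle, matrix protease, osteoclast-regulating, endothelial and lymphoid), the mean, the median and the direction of the test differed in sign.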

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

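No rule that singles out an array or a difference between contrasts was run, since groups held 3 arrays and the study has 1 contrast. The patterns below are the ones a reader of the gene lists would most want to follow. The covariate, the comparison with control 3 alone, the range within the controls and the contrast with S phase genes were chosen after the results were seen. With 10 splits of the 6 arrays into 3 and 3, no result can stand out at a share under 0.05.

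Mitosis and G2-M genes were 0.36 log2 units higher in Rs1 arrays, and the tests run cannot exclude cycling macrophages or unequal scaling as a source. The mean was 0.40 with the macrophage score of each array as a covariate, and 0.37 after quantile normalization. Both were past the preset threshold and neither with an estimated correlation (adjusted p = 0.624 and 0.550). Quantile normalization could change little, since the deposited arrays already had nearly equal quartiles. Macrophage markers were lower on average in Rs1 arrays (mean -0.77), so the covariate had no macrophage excess in Rs1 to remove. A larger share of cycling cells may account for the shift and stays open, since the list exceeded the S phase list by 0.31 but S phase genes need not follow that share as closely. Chance (1 of 10 splits, the real one at 0.36, the highest other 0.31) cannot be judged from so few splits, and an unequal make-up of the pools stays open too, since the controls alone spanned 0.40, although the groups did not overlap. The estimated correlation between members was 0.22, near the 0.2 at which simulated lists without a shift were called in 31% of cases. Those simulated calls used an unadjusted p under 0.05, a looser threshold than the adjusted one used for the list. The brightness of the histone-GFP gate, which could follow DNA content, was not tested.

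Macrophage markers were 0.77 log2 units below control on average, and 4 of the 10 splits gave a mean at least as large in size, the highest of the others at 1.55. Macrophages carried over unequally through the GFP sort are a candidate explanation, since the scores of the controls alone spanned 2.44, the groups overlapped, and members moved together (estimated correlation 0.90). The members with the highest signal were Tyrobp (10.85 in controls, 9.81 in Rs1) and Ctss (10.51 and 9.63), and the lowest was Cd163 (7.00 and 6.86), and signals of different probe sets do not measure abundance. No member of the 19-gene list is on another list, although how many of them osteoblasts also transcribe was not measured. Rs1 lowering macrophage transcripts stays open, since the mean was 0.54 against control 3 alone and 1 array excludes nothing.

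Osteoclast markers were 0.47 log2 units below control on average, and 3 of the 10 splits gave a mean at least as large in size, the highest of the others at 0.56. The controls alone spanned 0.72 and the groups overlapped, which an unequal make-up of the pools could give. The macrophage content of the pools may account for part of this, since with the macrophage score as a covariate the mean was -0.25, past the preset threshold (adjusted p = 0.00198) and not with an estimated correlation (adjusted p = 0.624). Against control 3 alone it was -0.01. A lower osteoclast content with Rs1 stays open.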

How the results depend on the processing

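The count of genes past the threshold was 0 under every alternative except without control 3, so leaving out 1 array gave 0 to 1. Genes at an unadjusted p under 0.05 numbered 626 with dim genes removed and 1819 over all probe sets, which test fewer and more features. In 10 of the 10 splits of the arrays the count past the threshold was at least the real 0 (highest other 1). No count can be below 0, so this outcome was fixed in advance and tests nothing. The unadjusted count was largest in the real split, 1 of the 10 (1149, highest other 1139), as was the list count (12, highest other 6), and 10 splits are too few to judge chance. The count of lists past camera ranged from 6 (without control 1) to 14 with 1 array left out. It was 5 without controls 1 and 2, 6 with the macrophage covariate, and 0 with an estimated correlation or fry. The mitosis mean of 0.36, the osteoclast mean of -0.47 and the macrophage mean of -0.77 were then unchanged by construction and not past (fry adjusted p = 0.183, 0.445 and 0.709). The macrophage mean ran from -1.43 to -0.21 with 1 array left out and was 0.54 without controls 1 and 2, where the osteoclast mean was -0.0081. The mitosis and stress lists passed the preset test in 16 of 16 other settings, with means from 0.28 to 0.52 and from -0.24 to -0.15. Over the 12 called lists, 141 of 191 values outside the set tests kept their call and direction, 49 kept only the direction and 1 turned. Of the 21 lists not past, 3 passed in some settings (cAMP-CREB in 8, early mesenchymal in 6, BMP and TGF-beta in 1 of 16). With the replicate number as a block, 0 genes and 8 lists passed, and 1293 genes had an unadjusted p under 0.05. Same-numbered arrays deviated with correlations of 0.15, 0.03 and 0.07, and arrays of unlike number with -0.14 to 0.07. Rs1 array 2 and control 3 correlated at 0.0695, above 0.0322 and 0.0694 with their own numbers. Macrophage scores fell from number 1 to number 3 in both groups. The labels name no pairing, so the main test used none, and a batch shared by number is not excluded. Of 1258 values of the 80 named genes, 1242 kept their direction and none passed. The 16 that turned belonged to 8 genes: Sost (0.0013) and Dkk1 (-0.0029) after quantile normalization; Sost (-0.094 to 0.074), Dkk1 (-0.080 to 0.25) and Col1a1 (-0.027 to 0.081) with 1 array left out; Dkk1 (-0.045) with the macrophage covariate; and Col8a1 (0.090), Cxcl10 (0.025), Ifit1 (0.0036), Gp5 (0.082), Lpl (0.055) and Dkk1 (-0.24) without controls 1 and 2. The cause was not tested. With its own score as a covariate the macrophage list is 0 by construction and is not counted, and a slide or scan block was not run because no source used here gives either. No detection value or background was used, so what signal over background limits is unknown.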

Other observations

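Several gene groups outside the lists fixed beforehand had positive mean differences in Rs1 osteoblasts. These 6 lists were drawn up after values had been seen, so their means and p-values are no independent evidence. The gene that led to a list was left out of its test, except for a proteasome list, drawn up with values in view and with no gene left out. Of its 19 subunit genes 17 were higher (mean 0.16), a count that is no independent evidence and is given without its p. Of 18 sterol synthesis genes 16 were higher (mean log2 difference 0.23), and Idi1, an enzyme of the isoprenoid branch that led to the list, differed by 1.15 ± 0.21 (± SE). The lower members of the sterol list were Insig1 (-0.28 ± 0.13) and Tm7sf2 (-0.25 ± 0.11). Of 21 ribosome biogenesis genes 18 were higher (mean 0.14), and Mak16, a nucleolar protein that led to the list, differed by 0.84 ± 0.16. With the preset correlation, camera's adjusted p over the 6 lists of this kind was 0.00257 and 0.0161 for these 2 lists, and with an estimated correlation the adjusted p was 0.188 for both. Of 16 genes of amino acid synthesis and transport 11 were higher (mean 0.14, adjusted p = 0.0289; 0.238 with an estimated correlation). Tubulins and stathmins (7 of 8 higher, adjusted p = 0.230) and glutathione and pentose phosphate enzymes (8 of 14 higher, adjusted p = 0.217) did not pass. Without control 1 none of the 6 lists passed the preset test, and the sterol mean was 0.15 (adjusted p = 0.0903), the ribosome biogenesis mean 0.14 (adjusted p = 0.0719) and the proteasome mean 0.11. The ribosome biogenesis call also ended without control 3 (mean 0.13, adjusted p = 0.0533) and the amino acid call without Rs1 array 1 (mean 0.08, adjusted p = 0.177). Without control 2 the glutathione list passed (mean 0.16, adjusted p = 0.0277, and 0.142 with an estimated correlation). Its mean was 0.05 with all arrays, -0.0055 without Rs1 array 1, -0.0031 without control 1 and -0.0058 without control 3.

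A hypothesis is that Rs1 osteoblasts may transcribe sterol synthesis and ribosome biogenesis genes at higher levels as groups. The tests, both chosen after the data were seen, gave means of 0.23 and 0.14 without the leading genes, in the direction of the hypothesis. That direction is no independent evidence, since the lists were drawn up after values had been seen. Neither list was past the threshold with an estimated correlation or without control 1, so the question stays open.

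Transcripts from the sex chromosomes differed between arrays within each group. Xist, transcribed from the inactive X chromosome, measured 5.60 (log2) on Rs1 array 3 and 9.94 to 10.99 on the other 5 arrays. The Y-linked gene Eif2s3y measured 4.17 on Rs1 array 2 and 4.32 on control array 1, against 7.06 to 8.37 on the other 4. With the mean of 3 Y-linked genes as a covariate, 0 genes and 12 lists passed, though not the same 12. The ribosomal protein call ended (mean 0.09, camera adjusted p = 0.0616). The cAMP and CREB list passed as lower (mean -0.13, camera adjusted p = 0.0254, and 0.672 with an estimated correlation).

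Principal components were computed over the genes with mean signal above the median of the 19935. The first component held 32.3% of the variance. Its scores were 24.9 for control 1 and 11.7 for control 2, and between -15.8 and -0.33 for the other 4 arrays. The mean log2 signal of the macrophage list was also highest in controls 1 and 2 (10.19 and 9.27). It lay between 7.75 (control 3) and 8.91 (Rs1 array 1) on the other 4. Among the 15583 probe sets outside the gene test, 0 had an adjusted p under 0.05.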
